A study of Oryza sativa Japonica Group with 8 samples.

How the data were processed

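RNA was sequenced from leaves of rice seedlings (cultivar Nipponbare, Japonica group) grown from seed on half-strength MS medium, a mineral salt medium, either with carbon dots at 0.56 mg/ml (CD) or without them (CK, the control). Carbon dots are carbon nanoparticles of a few nanometres. The labels give the seedlings as 2 weeks old and the growth protocol gives 3 weeks of growth, so the age at harvest is not settled here. The series lists 8 samples, of which 4 are RNA-seq libraries (2 CD and 2 CK) and 4 are bisulfite sequencing samples. DNA methylation was not analysed here.

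Raw read counts per gene were deposited by the authors in a table of 55801 genes on 12 chromosomes, laid out as featureCounts writes it and with no normalization, per the file headers. The TPM values deposited by the authors were tested against the count table: dividing counts by gene length and scaling each library to the same total gave the same values within 1e-05. The submitters' processing notes name FastQC 0.11.5, fastp 0.21.0, HISAT2 2.0.5, Bismark 0.23.0, Bowtie2, SAMtools 1.9 and featureCounts 1.6.4, with no role or order. The genome build and whether counting used strand are not given in the sources used here. Coordinates are those of the authors' count table. All rows name a gene, and no gene lies on the plastid or mitochondrial genome. Reads shared between near-identical copies could be split or lost by the counting, which concerns the CAB, RBCS, JAZ and RAB16 families.

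The 20 genes with most counts held 5.50% to 7.84% of a library. A chi-square test on counts gave 81.5 to 223.8 per degree of freedom for the 6 pairs of libraries, so no 2 libraries agree within sampling noise. The CD replicates gave 137.7, more than CD replicate 2 gave with CK replicate 1 (116.4) or CK replicate 2 (125.2). The labels do not say whether replicates came from separate plants or cultures, so p-values measure only the spread between these libraries, which could be technical.

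CD was compared with CK by edgeR 4.0.16 (R 4.3.3), with TMM normalization, the filterByExpr filter (26271 genes kept), the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are CD minus CK, with a standard error taken from the fold change and the square root of F. CPM values use TMM library sizes. Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists with 5 or more genes tested. These tests, the gene lists and the rule for named genes were fixed before the data were examined, as were the alternatives: RLE and total count scaling, no filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, limma with trend on log2(TPM + 1) or log2(TPM + 0.1), a replicate block, each library left out, the 20 genes with most counts left out, an adjusted p of 0.01, an estimated correlation, and fry. A crossed replicate pairing and list tests on matched members only were added after the data were seen. A lower bound on a fold used a floor of 3 counts over the group. Floors and counting intervals cover counting error only.

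The count table gives identifiers without names, and the reference table of names (assembly ASM3414082v1, another build, used for names only) pairs none of these identifiers with a symbol. List members were therefore entered by identifier and symbol before the data were examined, and each pair was checked in that table by symbol, chromosome, span and distance to neighbouring genes. Of 141 entries in 20 lists, 85 matched, 46 had no record, 6 had another span, 3 lay elsewhere and 1 was absent from the count table. Members that did not match stayed in the list tests and are not named. Another 12 lists defined by product descriptions alone had no member. A second family of 23 lists was written after the identifiers and some raw counts had been seen and before any test was run. It had 398 entries, of which, unlike in the first family, only the 245 that matched were kept. These hold 243 genes and were adjusted separately.

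Named genes were, per list, up to 3 called members, or the 2 with the highest mean CPM where none was called. Every measured gene of the DNA methylation list and the gene with the lowest adjusted p in each direction were also taken. Several genes shared the lowest adjusted p by edgeR (0.46), so the lowest unadjusted p decided. The rule's part on the largest called changes with a known product gave no gene. The list parts gave 51 genes, of which 30 had a matched symbol. CAB1R, CHLD, CHLI, PORA, PORB, DVR, NIA1, KSL7, KSL10, NPR1 and APX8 were chosen after their values were seen.

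The procedure was tested on simulated counts with the means, library sizes and dispersions of these libraries and 200 changed genes, on 25886 genes. edgeR recovered 0 of 50 genes changed 1.5-fold, 0 of 50 changed 2-fold, 31 of 50 changed 4-fold and 37 of 50 changed 8-fold, with 7 false calls among 75. DESeq2 recovered 3, 13, 42 and 42 of 50, with 73 false calls among 173. Where no gene had been changed, on 25862 genes, edgeR called 2 and DESeq2 called 28. The simulated dispersions were edgeR's own estimates per gene. In the measured libraries edgeR did not call even LOC_Os04g52440, at a log2 fold change of 6.27 (adjusted p = 0.46). The simulated recovery may therefore overstate that in these libraries. On simulated lists of 10 genes among 26271, camera at the preset correlation found 5 of 5 lists raised 2-fold, with an estimated correlation it found 0 of the 5, and fry found 2. The simulated genes were independent, so false list calls were not tested. The estimated correlation in the measured libraries was 0.938 for the light harvesting list and 0.941 for the chlorophyll synthesis list.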

Results

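Leaf transcriptomes were compared between 2 libraries from rice seedlings grown with carbon dots (CD) and 2 from seedlings grown without them (CK). Total counts were 74853055 and 49281927 in CD replicates 1 and 2, and 80317398 and 60763633 in CK replicates 1 and 2. The series title places the comparison in a study of how carbon dots act on the rice epigenome. In the CD libraries, the genes of light harvesting and chlorophyll synthesis stood lower as groups, and the genes of phytoalexin synthesis stood higher. These 3 list calls by camera were lost with an estimated correlation (adjusted p = 0.476 for each) and with fry (adjusted p = 0.291 for each). CD replicate 1 stood apart on the first principal component (46.6% of the variance). It lay at -76.4, against 2.3 for CD replicate 2 and 51.3 and 22.8 for the CK replicates. CD replicate 2 stood apart on the second (32.1%), at -67.8 against 19.3 for CD replicate 1 and 18.5 and 30 for the CK replicates. CD replicate 2 correlated across genes, which are not independent replicates, at 0.973 and 0.974 with the CK replicates and at 0.968 with CD replicate 1. No single gene passed the test over all 26271 genes. edgeR called 0 genes at an adjusted p of 0.05, with 2286 genes at an unadjusted p under 0.05 (876 higher and 1410 lower with carbon dots). That number was 880 without CK replicate 1, 1463 without CK replicate 2 and 4106 without CD replicate 2. Simulated counts with no gene changed gave edgeR 1234 genes at an unadjusted p under 0.05. Splitting the 4 libraries in the 2 ways that mix treated and control gave it 681 and 1427. Like edgeR, limma-voom called 0 genes at an adjusted p of 0.05. DESeq2 called 502 (199 higher and 303 lower, 183 and 206 of them by at least 2-fold).

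Photosynthesis genes had lower values with carbon dots. All 12 tested members of the light harvesting list had a log2 fold change below 0, with a median of -1.30, and the list fell by camera (adjusted p = 6.69e-15). That call was lost with an estimated correlation (adjusted p = 0.476). Over all genes edgeR called 0 members and DESeq2 called 4 lower, and 4 were lower by edgeR adjusted over the list alone. The symbols of 2 of the 12 members could be matched. CAB1R and CAB2R encode chlorophyll a/b binding proteins of the antenna. CAB2R averaged 528 ± 428 CPM with carbon dots and 1179 ± 806 CPM in the control (SD, n = 2), a log2 fold change of -1.16 ± 0.77 (SE), and CAB1R had -1.38 ± 0.86. CAB2R was at -0.21 without CK replicate 1, -0.51 without CD replicate 1 and -2.39 without CD replicate 2. Both CD libraries lay below both CK libraries for 8 of the 12 members. Chance separates the groups in either direction for 33.3% of genes, and 38.4% of all genes tested were separated here. The 12 members moved together (estimated correlation 0.938) and are not independent observations. The level of the list differed between replicates: relative to the mean of the 4 libraries it was -1.40 in CD replicate 1, -0.06 in CD replicate 2, 1.09 in CK replicate 1 and 0.37 in CK replicate 2 (log2). Its median was -0.71 without CD replicate 1 and -2.23 without CD replicate 2.

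The chlorophyll synthesis list fell too (camera adjusted p = 2.03e-11, or adjusted p = 0.476 with an estimated correlation). All 10 tested members were below 0 with a median of -0.93, and in all 10 both CD libraries lay below both CK libraries. Chance separates 33.3% of genes in either direction. These members moved together (estimated correlation 0.941), so the 10 are not independent observations. The list lay at -0.80 in CD replicate 1 and -0.15 in CD replicate 2, and its median was -0.63 without CD replicate 1 and -1.27 without CD replicate 2. Over all genes edgeR called 0 and DESeq2 called 1 lower, DVR, and 6 were lower by edgeR adjusted over the list alone. DVR (LOC_Os03g22780), the divinyl reductase that makes monovinyl chlorophyllide, averaged 9.01 ± 2.07 CPM with carbon dots and 21.0 ± 3.12 CPM in the control, a log2 fold change of -1.23 ± 0.24 (adjusted p = 0.0359 over the list alone, 0.46 over all genes by edgeR). It lies on chromosome 3 from 13155800 to 13157404. CHLD and CHLI, subunits of the magnesium chelatase, had -0.91 ± 0.25 and -0.96 ± 0.37, and CHLH, the large subunit, had -0.73 ± 0.34 (-0.37 without CD replicate 1, -1.20 without CD replicate 2). The protochlorophyllide reductases PORA and PORB had -1.04 ± 0.31 (-0.67 without CK replicate 1) and -1.24 ± 0.48. In the Calvin cycle list, too small for a list test and with no matched symbol, all 4 tested members were lower adjusted over the list alone, with a median of -1.35.

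**Figure D1:**
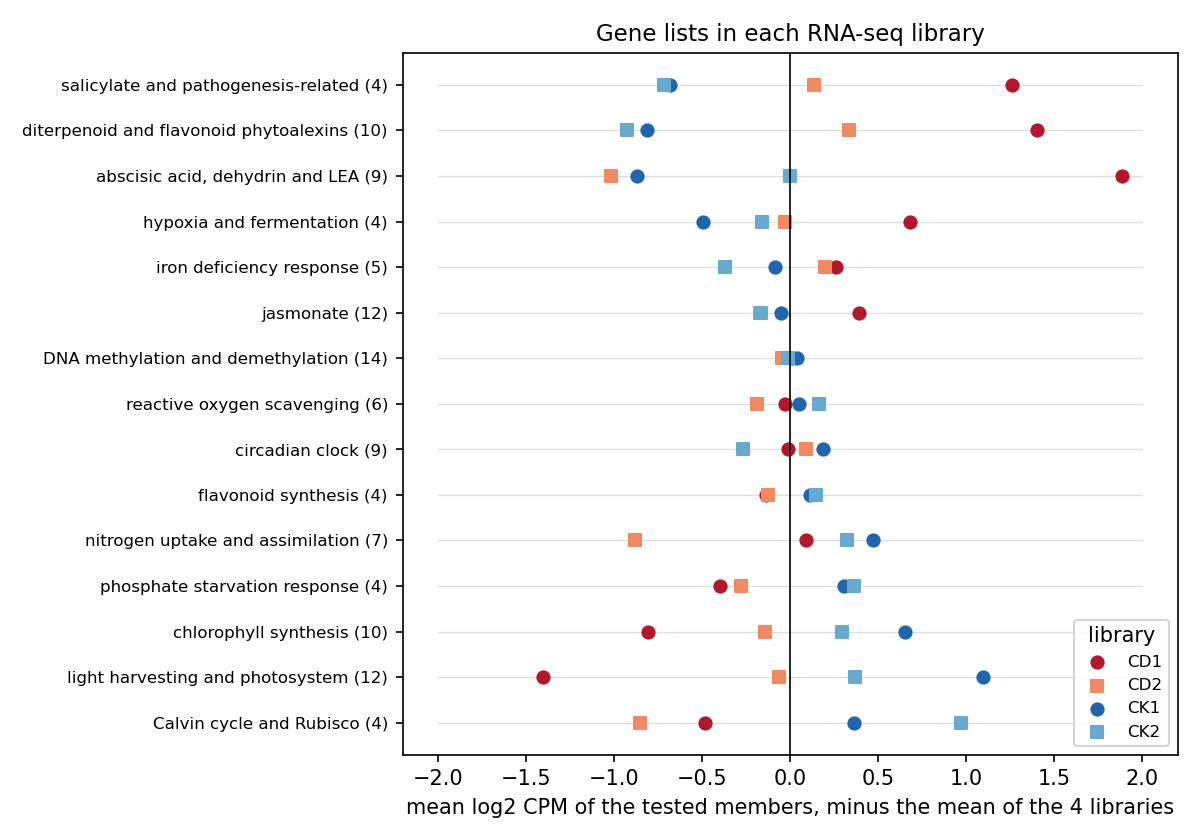
Each point is the mean log2 CPM of a list's tested members in one library minus the mean of the 4 libraries, with the number of members in brackets, for CD (red, orange) and CK (blue) libraries; no error bar is drawn. The light harvesting list lies at -1.40 and -0.06 in the CD libraries and at 1.09 and 0.37 in the CK libraries, and the DNA methylation list lies between -0.04 and 0.04 in all 4 libraries.

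Defence genes lay on the other side. The phytoalexin list, enzymes that build antimicrobial diterpenoids and a flavonoid, rose by camera (adjusted p = 7.68e-08), a call lost with an estimated correlation (adjusted p = 0.476) and with limma on log2(TPM + 1) (adjusted p = 0.0576, in a range of 8.95e-12 to 0.476 over all alternatives). Of 10 tested members 9 were above 0, with a median of 1.44, and 8 had both CD libraries above both CK libraries. Chance gives 33.3% for either direction, but these members are not independent observations either (estimated correlation 0.501). CD replicate 1 had the higher level, and the median was 0.80 without CD replicate 1 and 1.94 without CD replicate 2. edgeR called 0 members over all genes or adjusted over the list alone, and DESeq2 called 2 higher over all genes, CPS4 and KSL7. CPS4, the syn-copalyl diphosphate synthase of the momilactone pathway, was at 7.62 and 3.60 CPM with carbon dots and 1.74 and 0.77 CPM in the control, a log2 fold change of 2.16 ± 0.57. KSL7 and KSL10, kaurene synthase-like cyclases, had 4.33 ± 1.04 and 1.43 ± 0.53, from low levels. In the salicylate list, too small for a list test, all 4 tested members were above 0 and 2 were higher adjusted over the list alone. The list lay at 1.26 in CD replicate 1 and 0.14 in CD replicate 2. Its median of 1.76 was 0.67 without CD replicate 1 and 2.03 without CD replicate 2. PBZ1 (LOC_Os12g36880), a pathogenesis-related protein inducible by probenazole, on chromosome 12 from 22599952 to 22601258, averaged 88.3 ± 8.81 CPM with carbon dots and 23.1 ± 5.49 CPM in the control. Its log2 fold change was 1.93 ± 0.22 (adjusted p = 0.0012 over the list alone and 0.46 over all genes by edgeR, and 8.52e-09 over all genes by DESeq2). NPR1, the salicylate co-receptor, had 0.48 ± 0.23.

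The abscisic acid, dehydrin and LEA list rose by camera (adjusted p = 0.016, or adjusted p = 0.596 with an estimated correlation), with 8 of 9 members above 0 and a median of 1.05. The list lay at 1.89 in CD replicate 1 and at -1.02 in CD replicate 2, and without CD replicate 1 its direction turned (median -0.65, adjusted p = 0.224), while the median was 1.75 without CK replicate 2. It was no longer past the test without CK replicate 1 (adjusted p = 0.186), with total count scaling (0.0594), limma-voom (0.0643) or limma on log2(TPM + 1) (0.207) and log2(TPM + 0.1) (0.239), in a range of 4.98e-11 to 0.612 over all alternatives. SALT, a mannose-binding lectin induced by salt, was at 1032 CPM in CD replicate 1 and 345 CPM in CD replicate 2, against 185 and 109 CPM in the control (log2 fold change 2.23 ± 0.59, or 1.23 without CD replicate 1). The nitrogen list fell by camera (adjusted p = 0.0138, or adjusted p = 0.581 with an estimated correlation). It had 5 of 7 members below 0 and a median of -0.34. The list lay at 0.09 in CD replicate 1 and -0.88 in CD replicate 2, against 0.47 and 0.32 in the CK replicates. Over the 9 members present without a filter, its median was -0.07 by edgeR and turned to 0.045 with log2(TPM + 1). It was no longer past the test without CK replicate 1 (median -0.14, adjusted p = 0.0585), without the filter (0.0796), with limma-voom (0.0703) or with matched members only (0.0851), in a range of 4.65e-10 to 0.581. GS2 (LOC_Os04g56400), the plastid glutamine synthetase, on chromosome 4 from 33624332 to 33631095, averaged 688 ± 145 CPM against 1452 ± 217 CPM (log2 fold change -1.08 ± 0.26). The nitrate reductase gene NIA1 had -1.84 ± 0.62, and the cytosolic GS1.1 had -0.07 ± 0.22, which turned to 0.03 with total count scaling, 0.045 with TPM, 0.09 without CD replicate 1 and 0.05 without CK replicate 1, and was at -0.25 without CD replicate 2 and -0.17 without CK replicate 2.

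The listed genes of the DNA methylation machinery did not differ detectably, but the symbols of only 5 of the 14 tested members could be matched. DRM2 was the only methyltransferase among these 5, so the result for other methyltransferases rests on unmatched symbols. The list had 7 of 14 tested members above 0 and 7 below, a median of 0.02, a mean of -0.02 and a camera adjusted p of 0.99. edgeR called 0 of them over all genes or adjusted over the list alone, and DESeq2 called 0. The log2 fold changes were 0.05 ± 0.16 for AGO4A (-0.03 without CK replicate 2, 0.14 without CK replicate 1) and 0.09 ± 0.14 for AGO4B (0.05 without CK replicate 1, 0.15 without CK replicate 2), argonautes of RNA-directed DNA methylation, and 0.10 ± 0.19 for RDR2, its RNA polymerase (-0.06 without CK replicate 1, 0.29 without CK replicate 2). DRM2, the de novo methyltransferase, was at 36.1 and 40.6 CPM with carbon dots and 42.7 and 37.2 CPM in the control (log2 fold change -0.06 ± 0.16, which turned to 0.04 with total count scaling, 0.06 with TPM, 0.02 without CD replicate 1 and 0.05 without CK replicate 1, and was at -0.15 without CD replicate 2 or CK replicate 2). ROS1C, a DNA glycosylase of active demethylation, had -0.33 ± 0.23 (-0.09 without CD replicate 1, -0.61 without CD replicate 2). In simulated data edgeR recovered 0 of 50 genes changed 2-fold and 37 of 50 changed 8-fold. In the measured libraries it called no gene whatever its fold change, so the lack of calls alone does not exclude changes of any size. For the genes named here, the estimates and standard errors above limit the change more closely than the lack of calls, within the spread of these libraries.

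**Figure D2:**
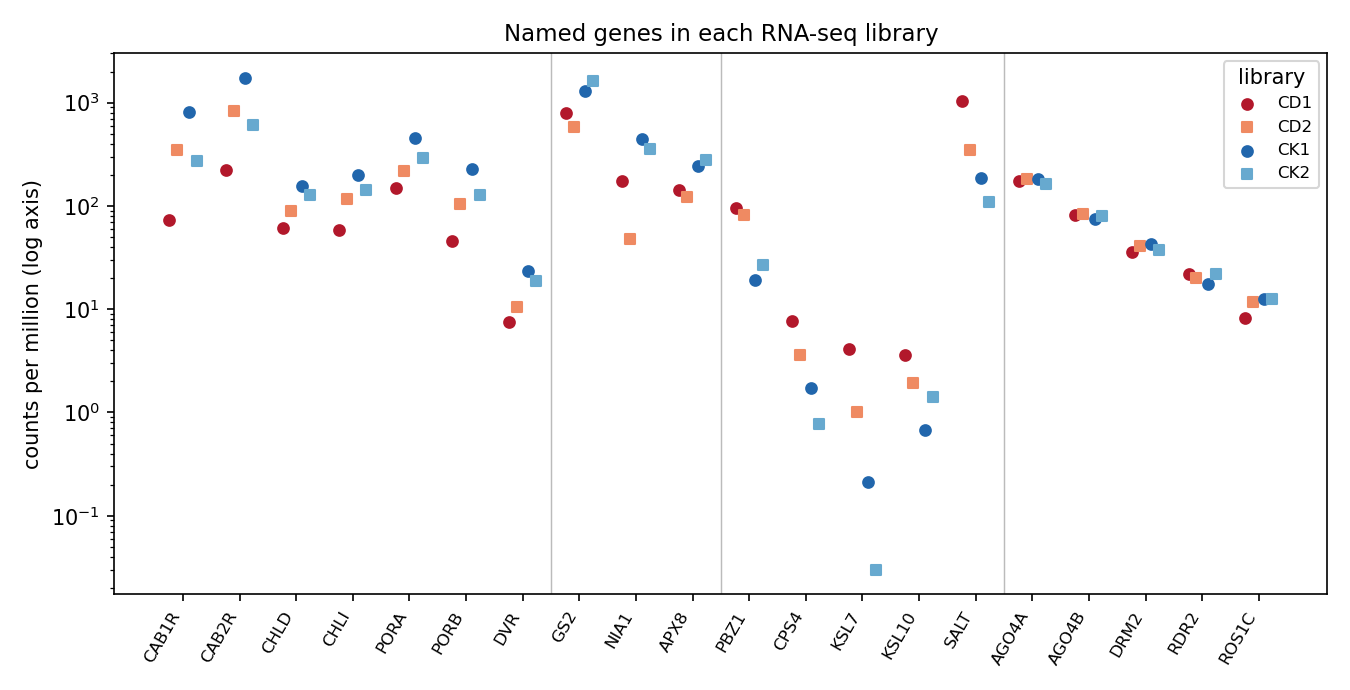
Normalised read counts (CPM) on a log axis for 20 named genes, 1 point per library, for CD (red, orange) and CK (blue); vertical lines part photosynthesis, nitrogen and redox, defence and stress, and DNA methylation genes. PBZ1 lies at 94.5 and 82.1 CPM in the CD libraries and at 19.3 and 27 CPM in the CK libraries, while AGO4A lies between 163 and 184 CPM in all 4.

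The remaining lists did not pass the camera test or were too small for it. Jasmonate (adjusted p = 0.118), iron deficiency (0.233), reactive oxygen scavenging (0.403) and the circadian clock (0.99, with a median of -0.08 and a mean of 0.04) were tested. Jasmonate passed without CD replicate 2 (adjusted p = 3.54e-04) and with matched members only (0.0343), and its direction turned without CD replicate 1 (adjusted p = 0.913). In these, JAZ6, a repressor of jasmonate signalling, had a log2 fold change of 0.15 ± 0.30 (-0.33 without CD replicate 1, 0.50 without CD replicate 2), NAS3, a nicotianamine synthase, -0.11 ± 0.41 (0.38 without CD replicate 1, -0.86 without CD replicate 2), APX2, a cytosolic ascorbate peroxidase, 0.23 ± 0.19, and the clock gene ELF3 -0.21 ± 0.18. Without CD replicate 1, APX2 was at 0.35 and ELF3 at -0.38, and without CD replicate 2 they were at 0.10 and -0.06. APX8, an ascorbate peroxidase, was lower adjusted over the list alone (-0.98 ± 0.18, adjusted p = 0.0153, or over all genes 0.46 by edgeR and 0.00367 by DESeq2). Among the small lists, the flavonoid genes CHS1 and CHI had -1.04 ± 0.42 and -0.67 ± 0.55, and the phosphate sensors SPX1 and SPX2 had -0.46 ± 0.15 and -0.47 ± 0.26. The fermentation genes ADH1 and PDC2 had 0.31 ± 0.27 and 0.08 ± 0.19, the chlorophyll breakdown gene SGR 0.38 ± 0.33, and the amylase gene AMY3D 0.10 ± 0.42. Of these, SGR turned to -0.01 and PDC2 to -0.06 without CD replicate 1, PDC2 to -0.06 and CHI to 0.04 without CK replicate 1, and AMY3D to -0.18 without CD replicate 2. SGR was at 0.68 without CD replicate 2 and 0.76 without CK replicate 1 but 0.09 without CK replicate 2, CHI at -0.18 without CD replicate 1, -1.43 without CD replicate 2 and -1.15 without CK replicate 2. PDC2 was at 0.20 without CD replicate 2 and 0.25 without CK replicate 2, and AMY3D at 0.35 without CD replicate 1. CHS1 was at -0.56 without CD replicate 1 and -1.76 without CD replicate 2, and SPX2 at -0.30 without CD replicate 2 and -0.20 without CK replicate 2. ADH1 was at 0.09 without CD replicate 1, 0.49 without CD replicate 2, 0.03 without CK replicate 1 and 0.66 without CK replicate 2.

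Markers of other tissues were measured beside these groups. The secondary wall cellulose synthases CESA4 and CESA7 had log2 fold changes of 0.12 ± 0.44 and 0.04 ± 0.40, which turned to -0.59 and -0.54 without CD replicate 2 and to -0.12 and -0.26 without CK replicate 2, and were at 0.60 and 0.45 without CD replicate 1 and 0.42 and 0.41 without CK replicate 1. The transporters LSI1 and NRAMP5, abundant in roots, had -0.27 ± 0.15 and -0.65 ± 0.33. NRAMP5 was at -0.34 without CD replicate 1, -1.05 without CD replicate 2 and -0.29 without CK replicate 2. PCNA, a replication clamp of dividing cells, had 0.06 ± 0.16 (-0.005 without CD replicate 1, 0.12 without CD replicate 2). OSH1 (LOC_Os03g51690), a homeobox gene of the shoot meristem on chromosome 3 from 29596277 to 29606861, had 0 counts in both CD libraries and 117 and 42 counts in the CK libraries. That is at least 50.3-fold lower with carbon dots against a floor of 3 counts over the group. By edgeR its adjusted p was 0.46 over all genes, 0.0452 without the filter, and 0.00276 over its list alone, which holds only 2 tested genes. By DESeq2 its adjusted p was 1.07e-04 over all genes.

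The genes with the lowest unadjusted p in each direction have no name in the sources used. The lowest adjusted p by edgeR, 0.46, was shared by other genes, PBZ1 and GS2 among them. LOC_Os10g13850, on chromosome 10 from 7529342 to 7530484, averaged 13.6 ± 0.91 CPM with carbon dots and 50.8 ± 2.97 CPM in the control (log2 fold change -1.90 ± 0.16, adjusted p = 0.46 by edgeR and 2.42e-13 by DESeq2). LOC_Os04g52440, on chromosome 4 from 31169012 to 31174731, averaged 10.6 ± 3.53 CPM against 0.141 ± 0.0907 CPM (log2 fold change 6.27 ± 0.56, adjusted p = 0.46 by edgeR and 4.57e-26 by DESeq2). All 502 DESeq2 calls had an unadjusted edgeR p under 0.05 and both CD libraries on one side of both CK libraries. Calls made on the same counts favour such genes, so this is no separate support for them. Such separation held for 38.4% of all genes tested against 33.3% by chance. Within groups, 3507 genes differed over 2-fold between the CD replicates and 2028 between the CK replicates. Total count scaling moved the median gene by 0.10 (log2) and turned the split at an unadjusted p under 0.05 to 1371 higher and 992 lower. TPM moved the median gene by as much and gave 1219 higher and 879 lower.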

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

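The tests with a crossed pairing, with matched members only and on the added lists were chosen after seeing the data. Of the alternatives run, only edgeR with no filter, which called 29 genes (14 higher, 15 lower), and DESeq2, which called 502 (199 higher, 303 lower), called any gene. The cause was not tested for the calls without the filter. For DESeq2, a test of spread between single libraries, given below, could not decide. Leaving out each library gave 0 to 0 genes, with 880 to 4106 at an unadjusted p under 0.05 (880 without CK replicate 1, 1463 without CK replicate 2, 4106 without CD replicate 2, against 2286). The lone library left in a group is assumed there to vary like the other group. The labels name no pairing of replicates. Deviations of the same-numbered replicates correlated at -0.141 and those of the crossed ones at 0.141. With 2 libraries per group these are 1 value with opposite signs, which cannot show whether replicates were handled together. With the replicate block, 0 genes and 5 lists were called, as without it, and 4 added lists instead of 2. A crossed pairing as a block called 0 genes, 5 lists and 5 added lists. Of the fixed lists, 5 passed (2 higher, 3 lower), and leaving out each library gave 4 to 7 (1 to 4 higher, 2 to 3 lower). The number past the test was 3 (1 higher) with limma-voom and 3 (0 higher) with log2(TPM + 1). The number of lists higher was 1 with total count scaling, 1 with log2(TPM + 0.1) and 4 without the filter. Matched members only left 1 list lower, because light harvesting then had too few members to test and nitrogen no longer passed (adjusted p = 0.0851). An estimated correlation and fry left 0 lists in either direction and 0 added lists, where the estimated correlation also found no raised list in simulated data. The light harvesting and chlorophyll synthesis lists passed in the same direction in each alternative that tested them except these 2. The abscisic acid list reversed without CD replicate 1 (adjusted p = 0.224), and ranged from 4.98e-11 to 0.612 over its alternatives. The 2 added lists became 3 with DESeq2, 1 with log2(TPM + 1), 1 with log2(TPM + 0.1), and 1 to 6 with a library left out. Except where a cause is given, the cause of these changes was not tested. Of 570 values of 36 named genes under an alternative, 529 kept their sign and side of the threshold, 13 passed it with DESeq2 or without the filter, and 28 turned sign without passing it. Leaving out plastid and mitochondrial genes was not run, since the count table holds none.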

Other observations

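The tests on other cell types, harvest time and depth were chosen after the results were seen, as was the CPM limit on shoot apex markers, and all lists in this paragraph are of the family written after identifiers had been seen. Plastid development genes were lower as a group: all 7 members of the chloroplast biogenesis list were below 0, with a median of -0.62 (camera adjusted p = 8.05e-04, or adjusted p = 0.73 with an estimated correlation). DXR, an early enzyme of plastid isoprenoid synthesis, had a log2 fold change of -0.70 ± 0.16 (SE) and was the 1 member lower adjusted over the list alone (adjusted p = 0.0454). The carotenoid genes PSY1 and PSY2 had -0.62 ± 0.18 and -0.84 ± 0.28, and the transcription factor GLK1, which drives chloroplast development, -0.62 ± 0.22. A defence list that holds chitinases (CHT8 at 1.35), chitin receptors (CERK1 at 0.36) and MAP kinases (MPK3 at 0.84) was higher (adjusted p = 0.0132, or adjusted p = 0.73 with an estimated correlation), with 8 of 11 members above 0 and a median of 0.84, and was no longer past the test without CD replicate 1 (adjusted p = 0.243), without CK replicate 1 (0.14) or with limma on log2(TPM + 1) (0.173) and log2(TPM + 0.1) (0.154), in a range of 8.59e-06 to 0.73.

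Single genes of metal, sodium and gibberellin metabolism stood apart adjusted over the list alone. That adjustment does not allow for the number of lists searched, here or for the members given above. NAAT1, which makes a precursor of iron-chelating phytosiderophores, was at 80.7 and 74.3 CPM with carbon dots and 40.1 and 37.7 CPM in the control (log2 fold change 1.00 ± 0.15, adjusted p = 0.00836). The sodium transporter HKT2.1 had 1.98 ± 0.32 (adjusted p = 0.0159) and HKT1.3 had -1.12 ± 0.25 (adjusted p = 0.0318). CPS1, the copalyl diphosphate synthase of gibberellin synthesis, was at 0.49 and 0.56 CPM against 2.38 and 2.35 CPM (-2.17 ± 0.34, adjusted p = 0.0136). None of these 4 passed over all genes by edgeR and all 4 did by DESeq2, and they were chosen after their values were seen. Of the other added lists, none passed (lowest adjusted p = 0.0766, ethylene). The sign of the median differed from the direction of the camera test for iron homeostasis, auxin, and reactive oxygen and redox.

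The lower photosynthesis genes could reflect the treatment, the hour of harvest or a change of cell types. A lower share of mesophyll cells predicts higher markers of other cell types: the median of 10 dividing cell markers was -0.10 and their mean -0.10 ± 0.08 (SE over libraries), but the mean of 3 vascular markers was 0.01 ± 0.60, too wide to exclude a rise, so this stays open. The hour stays open: the evening gene GI minus the median of the day genes PRR73 and PRR37 was 0.49 ± 0.44, and a first version of this contrast, dropped because its symbols had not matched, was -0.73 ± 0.37. Of the 3 splits of the 4 libraries, 1, the real one, gave a camera p as small for the light harvesting list (6.69e-16, against 5.22e-06 for the next), and 3 splits are too few for a share under 0.05. The other splits passed 4 and 3 fixed lists against 5 in the real one, among them light harvesting (adjusted p = 2.61e-05) and chlorophyll synthesis (0.0133) in the split of CD replicate 1 and CK replicate 2 against the others, and phytoalexins (0.0316) in the split by replicate number, so camera at the preset correlation also calls these lists on differences between libraries that are not the treatment.

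OSH1 and PLA1 (LOC_Os10g26340), a cytochrome P450 gene of young leaf primordia, were counted almost only in the control: PLA1 had 1 and 0 counts in the CD libraries and 208 and 64 in the CK libraries, 258-fold lower with carbon dots (95% counting interval 45.9 to 10200). Depth does not account for this, since 234 counts of the pair were expected in the CD libraries at the lower control rate and 1 was seen. A candidate explanation is shoot apex tissue in the control samples, but the test fixed beforehand, the summed CPM of 9 other apex markers, gave a control to CD ratio of 1.04, which met the bound set for its absence. ROC5 alone, at 117 to 144 CPM in each library, held 78.5% of the sum, so that test mostly measured ROC5. The 4 markers under 1 CPM (OSH6, OSH15, PLA2 and LAX1, with 25 counts in CD and 234 in CK) gave a ratio of 8.22. OSH15 had 24 counts in CD and 143 in CK, OSH6 0 and 71, PLA2 0 and 20, and LAX1 1 and 0. The 5 markers under 3 CPM gave 1.95. The 7 under 10 CPM, which leave out ROC5, gave 1.1 and also met the bound for absence, so the first result does not rest on ROC5 alone. More abundant markers weigh most in these sums too. OSH71 alone was at 2.37 and 1.49 CPM in CD and at 2.12 and 2.79 CPM in CK. The ratio thus depends on a limit chosen after the results were seen. This explanation stays open, as does lower expression in treated seedlings.

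DESeq2 called 502 genes where edgeR called 0. The calls could come from spread between single libraries: among the other 2 splits of the libraries, which mix treated and control seedlings, DESeq2 called up to 288 genes (6 in the other), while edgeR called 0 in each. The split with 288 sets CD replicate 1 and CK replicate 2 against the other libraries, so a structure of the libraries that is not the treatment gives calls too. How many of the 502 it accounts for cannot be told apart here, since real treatment effects add to the spread in those splits.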
